A study of Homo sapiens with 8 samples.

How the data were processed

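RNA of 2 renal carcinoma lines, 786-O and Caki-1, each kept beside siCont or siINSR endothelial cells, was labelled with Cy3 and hybridised to 8 one-colour Agilent arrays, 2 for each of the 4 groups, per the labels' protocols. The protocol in the labels names a Caki-1 cell suspension for every sample; the line of each array was taken from its title. The scanner files were made with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. Their values are spot intensity on a linear scale, background-subtracted and spatially detrended within each array in the processed column, per the file headers, and not normalized between arrays. The authors also deposited a table of log2 values per probe. Set against the scanner files, it equals log2 of the processed signal minus 1 constant per array for between 99.5% and 99.7% of probes (within 0.001), with each column's 75th percentile over all probes at 0 within 0.001. Its column medians were between -1.33 and -1.28 for the 786-O columns and between -4.08 and -4.00 for Caki-1. Its scale, centring and direction are thus known from the values; the values are not centred by gene.

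The 60901 non-control spots hold 58201 probes. The files give accessions and no gene symbols, so a probe was named where its unversioned RefSeq accession was in a RefSeq gene table of assembly GRCh38.p14; 31104 probes matched, covering 22439 genes. The array files name hg19, so no coordinates are given. Unnamed probes were left out of the tests. Between 88 and 173 spots per array carried a non-uniformity or population outlier mark and were left out, which removed 10 probes. No spot was saturated.

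The plan fixed before the data were examined scaled each array by the 75th percentile of all non-control probes. Only 18.5% to 44.2% of the probes were detected per array, so the percentile was taken instead over the 7987 probes well above background on all 8 arrays, with all probes as an alternative. Processed signals were divided by this percentile and multiplied by the geometric mean of the 8 percentiles, floored at 1 and put on the log2 scale, and spots of a probe were averaged. A probe was kept if it was well above background on both arrays of at least 1 group, which left 26457 probes, 19593 of them named. A gene was represented by its kept probe with the highest mean over the 8 arrays, giving 14838 genes, of which 3829 had several kept probes. A gene is called measured in a comparison where the probe tested was well above background on both arrays of at least 1 group of that comparison, and in both lines for comparisons over both. Where a gene was below background in 1 group, its fold is a bound: the mean of the bright group against, per array of the dim group, the higher of the lowest signal among probes well above background and its own signal.

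Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 4 group means over all 8 arrays, 4 residual degrees of freedom, prior degrees of freedom 1.91), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The comparisons were siINSR against siCont in each line, their average, their difference, and Caki-1 against 786-O beside siCont cells. The 34 gene lists were fixed before the data were examined, updated to current symbols, and tested with camera (preset correlation 0.01, at least 5 genes tested, adjusted over lists), camera with an estimated correlation, and fry. The set test on the difference between lines was added after the data were seen. Numbers of members are given over all genes and adjusted over the list alone.

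The genes named were chosen by a rule written before the data were examined. For each line and the average these were the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose siINSR arrays lay on one side of the siCont arrays of the same line. For the difference between responses and between lines it was 8 per direction, and genes called the same way in both lines were to be named as well (there were none). With fewer than 5 in a direction, the 5 with the smallest p were named as not passing. Up to 4 members per list discussed and INSR, IGF1R, IRS1, IRS2 and VEGFA were always named. Unplaced and antisense transcripts, XIST and genes on the Y chromosome were left out of naming, as were genes whose probes passed in opposite directions (0 in either line). Genes named outside the rule are marked as such. Of the genes the rule selects for the difference between lines, 1 per direction is left out of the text.

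On simulated data for the Caki-1 comparison, with the real group means and residual spreads of 14838 genes, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale, limma recovered 8.96%, 52.2% and 71.2% of them, with 5 calls among the other genes. The other genes included some given a smaller shift to try the set test, so not each of the 5 need be false. All arrays were on 1 slide with 1 scan, so no slide or scan block could be fitted; lines lay in separate rows of the slide and groups in separate columns, so position and group cannot be told apart. The alternatives covered background correction, scaling, the filter, the rule for several probes, the estimate of the spread, array weights, a replicate block, the authors' table and each array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.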

Results

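Gene expression was measured on 8 one-colour arrays from 2 human clear cell renal carcinoma lines, 786-O and Caki-1. Each line had been kept for 24 h in the lower well of an insert co-culture, with human renal glomerular endothelial cells on the insert above it. The endothelial cells had received either a non-silencing duplex (siCont) or 10 nM of siRNA against the insulin receptor gene INSR (siINSR), 72 h before they were seeded. The design therefore asks how tumour cells respond, without direct contact, to endothelial cells given siRNA against the insulin receptor. The knockdown itself was not measured on these arrays. There were 4 groups of 2 arrays. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. All 8 arrays shared 1 slide. On the 4 Caki-1 arrays, between 42.2% and 44.2% of the 58201 probes were well above background, against 18.5% to 19.1% on the 4 arrays labelled 786-O. The number of arrays limits the precision of every value.

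INSR itself was read first in both lines. The siRNA was given to the endothelial cells, which were not put on the arrays, so INSR in the tumour cells checks no label. In Caki-1, the log2 signal of INSR was 3.95 ± 0.11 (SD, n = 2) beside siCont and 3.71 ± 0.36 (SD, n = 2) beside siINSR endothelial cells, a log2 change of -0.24 (SE 0.20, limma unadjusted p = 0.278, not past the threshold after adjustment). Without Caki-1_siINSR replicate 2 the log2 change was 0.01, without Caki-1_siINSR replicate 1 -0.49, without Caki-1_siCont replicate 2 -0.16 and without Caki-1_siCont replicate 1 -0.33. On the arrays labelled 786-O it was 8.00 ± 0.21 (SD, n = 2) and 7.70 ± 0.13 (SD, n = 2), a log2 change of -0.30 (SE 0.20, limma adjusted p = 0.655). It was -0.15 without 786-O_siCont replicate 1, -0.46 without 786-O_siCont replicate 2, -0.40 without 786-O_siINSR replicate 1 and -0.21 without 786-O_siINSR replicate 2. The insulin-like growth factor receptor IGF1R and the adaptors IRS1 and IRS2 were well above background on the Caki-1 arrays, with log2 changes of -0.03, 0.04 and 0.08, none past the threshold in limma. These 3 genes were not well above background on any array labelled 786-O. The SE of each gene pools the spread within all 4 groups, so noise at background on those arrays enters the Caki-1 tests as well. For IGF1R the SDs (n = 2 each) were 0.015 and 0.045 in the Caki-1 groups and 1.08 and 0.67 in the 786-O groups. The SE of its Caki-1 change was 0.53. The log2 change of VEGFA, the main angiogenic growth factor, was -0.34 (SE 0.14, limma adjusted p = 0.869) in Caki-1 and 0.01 (SE 0.14, limma adjusted p = 0.984) on the arrays labelled 786-O.

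In Caki-1 cells beside siINSR endothelial cells, the genes of DNA replication, the interferon response and cell division were shifted upward as groups, and the genes of ribosomal proteins, metallothioneins, HIF targets and the unfolded protein response downward. These were 7 of the 34 gene lists tested, by camera with a preset correlation of 0.01. None of the 7 passed with an estimated correlation, where each had adjusted p = 0.787, and fry called none of the 34 lists for a shift in one direction. The shifts were small, with list medians between -0.22 and 0.20 on the log2 scale, and no list member passed limma's threshold over all 14838 genes tested. Of the endothelial markers, which could report carry-over of the cells above the insert, 8 were measured in Caki-1, with 5 higher and 3 lower and a median log2 change of 0.085.

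The DNA replication list had the largest upward median. Of its 30 measured members, 29 had a positive log2 change, with a median of 0.20 (camera adjusted p = 4.78e-06; adjusted p = 0.787 with an estimated correlation). No member passed when adjusted over the list alone. The members with the smallest p were POLE2, a subunit of DNA polymerase epsilon, at 0.55 (SE 0.15), the replicative helicase subunit MCM3 at 0.41 (SE 0.14), the transcription factor E2F1, which drives S-phase genes, at 0.35 (SE 0.13), and GINS3, part of the same helicase complex, at 0.31 (SE 0.12). In the cell division list, 28 of 29 measured members had a positive log2 change, with a median of 0.13 (camera adjusted p = 0.000983; adjusted p = 0.787 with an estimated correlation), and none passed when adjusted over the list alone. Examples were the spindle checkpoint kinase BUB1B at 0.23 (SE 0.11), the kinetochore proteins NDC80 at 0.27 (SE 0.14) and CENPF at 0.22 (SE 0.12), and the mitotic cyclin CCNB1 at 0.24 (SE 0.15). The cell division call was lost without Caki-1_siCont replicate 1 (median 0.06, adjusted p = 0.307) and without Caki-1_siINSR replicate 2 (median 0.10, adjusted p = 0.160).

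In the interferon response list, 23 of 27 measured members had a positive log2 change, with a median of 0.18 (camera adjusted p = 0.000181; adjusted p = 0.787 with an estimated correlation). Adjusted over the list alone, 1 member passed. The antiviral GTPase MX1 changed from 7.19 ± 0.10 (SD, n = 2) to 7.85 ± 0.09 (SD, n = 2), a log2 change of 0.66 (SE 0.12) with a limma adjusted p of 0.518 over all genes. OAS1, which makes the activator of RNase L, had a log2 change of 0.58 (SE 0.14), IFI6 0.47 (SE 0.14) and IFIT2, which binds viral RNA, 0.37 (SE 0.12), and none of these passed over all genes.

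**Figure D1:**
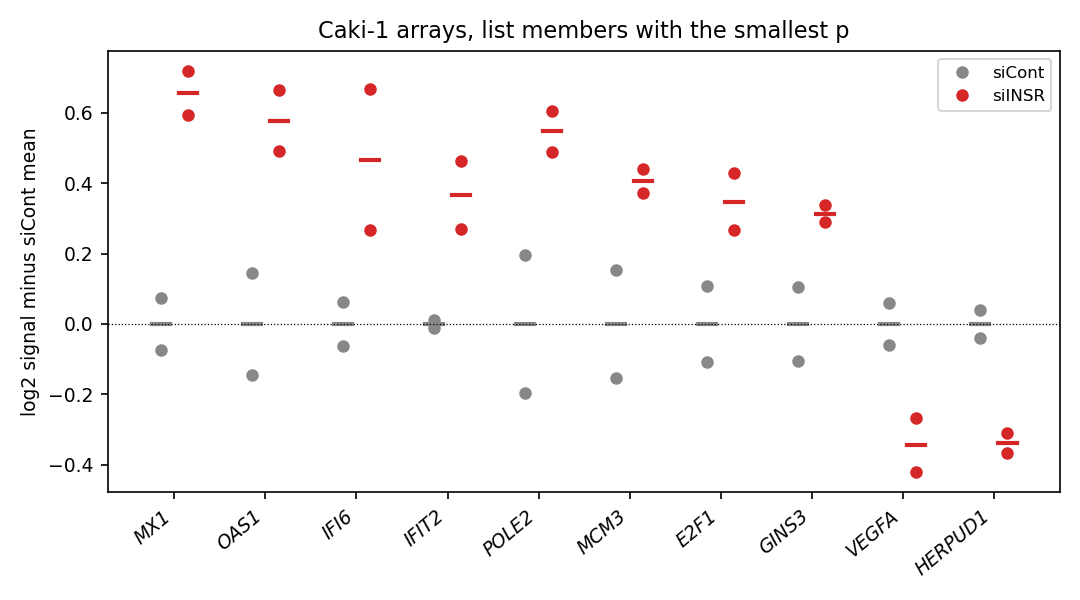
Log2 signal of 10 list members on the 4 Caki-1 arrays, each minus the mean of the 2 siCont arrays of that gene, with 1 point per array and a bar at each group mean. The members were chosen for the smallest p in their lists, so the separation of the points follows in part from that choice. For the 8 members of the interferon response and DNA replication lists both siINSR points lie above both siCont points, with MX1 0.66 higher on average, and for VEGFA and HERPUD1 both lie below.

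The ribosomal protein list had a negative log2 change in 31 of 33 measured members and a median of -0.14 (camera adjusted p = 2.01e-06; adjusted p = 0.787 with an estimated correlation). Its members with the smallest p were RPS2 at -0.32 (SE 0.12), RPS27 at -0.28 (SE 0.12), RPL38 at -0.27 (SE 0.11) and RPL13 at -0.24 (SE 0.11). These are among the brightest probes of the array, and the call was lost under quantile normalization (adjusted p = 0.946). It was also lost when a trend of the fold change with signal level was taken out (median -0.02, camera adjusted p = 0.906). All 10 measured genes of the metallothionein list, mostly small metal-binding proteins, had a negative log2 change, with a median of -0.22 (camera adjusted p = 0.00109; adjusted p = 0.787 with an estimated correlation), among them MT1B at -0.27 (SE 0.11) and MT1A at -0.19 (SE 0.09). Paralogous metallothionein transcripts are close in sequence, so their probes may not separate them. This call was lost without Caki-1_siCont replicate 1 (median -0.13, adjusted p = 0.217), without Caki-1_siINSR replicate 1 (median -0.20, adjusted p = 0.0650), under quantile normalization (adjusted p = 0.0701) and without a filter on dim probes (adjusted p = 0.0864).

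HIF targets, the genes switched on by the hypoxia-inducible factors, had a median log2 change of -0.14, with 17 of 22 measured members negative (camera adjusted p = 0.00945; adjusted p = 0.787 with an estimated correlation). The members with the smallest p were VEGFA at -0.34 (SE 0.14), the collagen cross-linking enzyme LOX at -0.48 (SE 0.21), the lipase inhibitor ANGPTL4 at -0.26 (SE 0.12) and the vasodilator peptide gene ADM at -0.38 (SE 0.19). The call was lost without Caki-1_siCont replicate 1 (median -0.09, adjusted p = 0.323), without Caki-1_siINSR replicate 1 (median -0.07, adjusted p = 0.642), under quantile normalization (adjusted p = 0.0834) and without a filter on dim probes (adjusted p = 0.300). In the unfolded protein response list, 14 of 19 measured members were negative, with a median of -0.07 (camera adjusted p = 0.0394; adjusted p = 0.787 with an estimated correlation). Examples were HERPUD1, which acts in the degradation of misfolded proteins of the endoplasmic reticulum, at -0.34 (SE 0.08), and the co-chaperone DNAJC3 at -0.26 (SE 0.09). This call was lost whichever of the 4 Caki-1 arrays was left out, with adjusted p from 0.104 to 0.217, and without 3 of the 4 arrays labelled 786-O (adjusted p from 0.0609 to 0.0916). It was also lost under quantile normalization (adjusted p = 0.164), without a filter on dim probes (adjusted p = 0.525), with normexp (adjusted p = 0.197), among probes above background on all arrays (adjusted p = 0.411), with only the arrays of the line (adjusted p = 0.0680) and with the replicate block (adjusted p = 0.0854), in 14 of 22 settings in all. When a trend of the fold change with signal level was taken out, the HIF target and unfolded protein response calls were lost (camera adjusted p = 0.116 and 0.184). No member of the 4 downward lists passed when adjusted over the list alone. The insulin and IGF signalling list had a median log2 change of 0.03 and the FOXO targets, genes held down by insulin signalling, -0.07, and neither passed (camera adjusted p = 0.908 and 0.140).

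**Figure D2:**
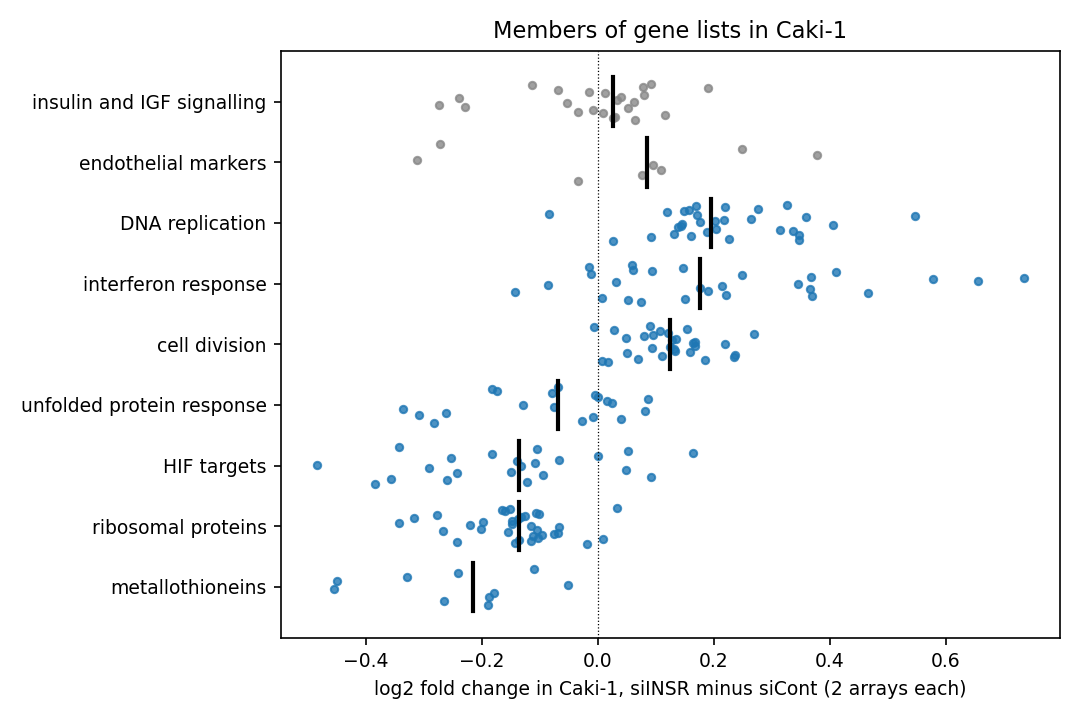
Log2 fold change in Caki-1, siINSR minus siCont with 2 arrays in each group, for the measured members of 9 gene lists, with 1 point per gene and a black bar at the list median. The 7 lists in blue passed camera with the preset correlation, with medians from -0.22 for metallothioneins to 0.20 for DNA replication, and the 2 in grey, endothelial markers and insulin and IGF signalling, did not.

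Gene by gene, 3 of 14838 genes passed limma's adjusted p threshold of 0.05 in Caki-1, all higher beside siINSR endothelial cells. CCT8L2, a chaperonin-like gene, was well above background on both siINSR arrays and on neither siCont array, and was at least 1.84-fold higher (limma adjusted p = 0.00385). The selenium carrier gene SELENOP (limma adjusted p = 0.0303) and the small nucleolar RNA SNORA2B (limma adjusted p = 0.0425) were not well above background on any Caki-1 array, so no fold is given for them. Among genes that did not pass, MTX3 was at least 1.03-fold higher (limma adjusted p = 0.241), and EPIST (limma adjusted p = 0.241) was well above background on 1 siINSR array. In the other direction no gene passed. The neuronal calcium sensor gene VSNL1 was well above background on the siCont arrays alone and at least 2.19-fold lower beside siINSR endothelial cells (limma adjusted p = 0.182), while NRN1 (limma adjusted p = 0.0566), FGFR2, FN3K and DCST2 (limma adjusted p = 0.241 for each of these 3) were not well above background on both arrays of either group. At an unadjusted p under 0.05 there were 839 genes, 451 higher and 388 lower, against 742 expected by chance. The number of genes past the threshold, and its direction, changed with single arrays. It was 5 higher and 30 lower without Caki-1_siCont replicate 1, 4 and 13 without Caki-1_siCont replicate 2, 11 and 3 without Caki-1_siINSR replicate 1, and 37 and 4 without Caki-1_siINSR replicate 2. It was 0 when the 4 Caki-1 arrays were fitted alone, with the replicate block, after quantile normalization and among probes above background on all arrays, and 2 with normexp, neither of them among the 3. The count was 1 with the percentile over all probes, with no filter and among measured genes, and 14 with array weights (9 higher, 5 lower). It was 0 without 786-O_siCont replicate 1 and 1 without any 1 of the other arrays labelled 786-O.

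The arrays labelled 786-O stood apart from the Caki-1 arrays in which probes gave signal. Of 23427 probes well above background on all 4 Caki-1 arrays, 13803 were so on none of the 4 arrays labelled 786-O, while 781 of 9340 probes went the other way. The genes in this and the next paragraph were chosen after their values were seen. Probes of genes active in nearly all cells were among those without signal. The probes of the tubulin gene TUBA1B, HPRT1, the transferrin receptor gene TFRC and GUSB were not well above background on any array labelled 786-O. They had Caki-1 means of 15.11, 10.97, 11.85 and 12.04 on the log2 scale. GAPDH had a mean of 7.82 ± 0.09 (SD, n = 4) on the arrays labelled 786-O and 16.04 ± 0.14 (SD, n = 4) on the Caki-1 arrays. Other genes of this kind kept strong signal. The probes of EEF1A1, PPIA and ACTB brightest on the arrays labelled 786-O lay at 17.56, 17.13 and 16.56, against 16.68, 15.45 and 16.17 in Caki-1. Another PPIA probe lay at 2.28, against 15.79 in Caki-1. The renal lineage factor PAX8, the hypoxia-inducible factor gene EPAS1 and the epithelial keratin gene KRT18 were likewise at background on the arrays labelled 786-O, with Caki-1 signal of 11.31 for PAX8, 13.36 for EPAS1 and 10.99 and 13.29 for the 2 probes of KRT18. In contrast, the renal tubule lineage genes LRP2 and AQP1 had a probe at 9.89 and 10.51 on the arrays labelled 786-O, against 9.03 and 2.66 in Caki-1.

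Probes of 1 gene often disagreed on these arrays. The lactate dehydrogenase gene LDHA had 1 probe at 14.67 and 1 at 1.93 on the arrays labelled 786-O, and 14.04 and 15.78 in Caki-1. Among 1112 genes with at least 2 probes, all bright on the Caki-1 arrays, 40.3% (Wilson 95% interval 37.4% to 43.2%) had 1 probe above background on all 4 arrays labelled 786-O and another on none. In the opposite direction this held for 2.02% of 198 genes (Wilson 95% interval 0.788% to 5.08%), where far fewer probes were lost. Among genes that lost any probe, the split genes were 448 of 851 and 4 of 9. Replicates agreed closely, with Pearson r of at least 0.995 between any 2 arrays of a line over the 7987 probes detected on all arrays, against 0.630 to 0.635 between lines. These correlations are across probes, which are not independent replicates.

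**Figure D3:**
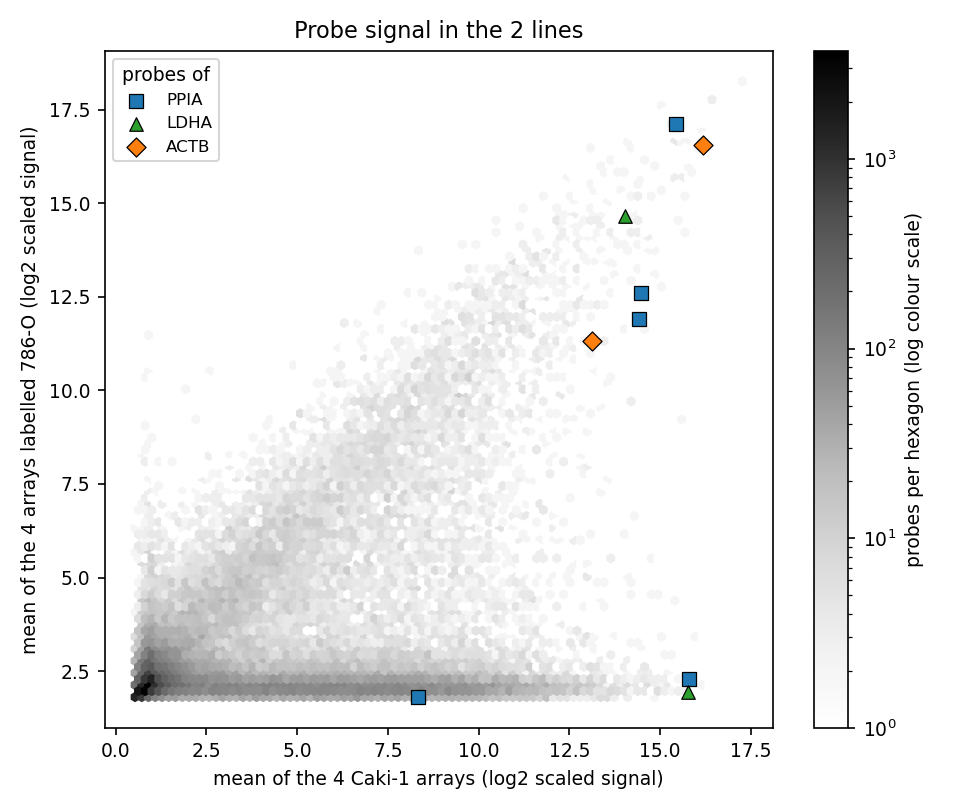
Mean log2 scaled signal of each probe over the 4 Caki-1 arrays (horizontal) and the 4 arrays labelled 786-O (vertical), with the grey level giving the number of probes and coloured symbols the probes of PPIA, LDHA and ACTB. A band of probes runs along the bottom, bright in Caki-1 and at background on the arrays labelled 786-O, and it holds 1 probe of LDHA at 1.93 while the other probe of this gene lies at 14.67.

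On the arrays labelled 786-O, 51 genes passed limma's threshold, 18 higher and 33 lower beside siINSR endothelial cells. For 45 of the 51 the probe tested was not well above background on both arrays of either 786-O group. The remaining 6 were 2 higher and 4 lower. Of these, ONECUT1, a liver and pancreas transcription factor gene, was at least 1.17-fold higher (limma adjusted p = 0.0418). MGAM2, a maltase-glucoamylase gene, was at least 2.58-fold lower (limma adjusted p = 0.0134) and the centromere protein gene CENPI at least 1.51-fold lower (limma adjusted p = 0.00751). IGF2, the insulin-like growth factor gene, was lower as fitted, from 4.88 ± 0.15 to 3.22 ± 0.13 (SD, n = 2 each, limma adjusted p = 0.0134), but the probe tested was below background on both siINSR arrays while another IGF2 probe was above it there, so no bound on the fold is given. The other 2, named after their values were seen, were COG1, with a log2 change of -1.24 (limma adjusted p = 0.0375), and the non-coding LINC01238, at 1.45 (limma adjusted p = 0.0471).

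For the other called genes named here, the probe tested was not measured on the arrays labelled 786-O. Those higher were WFDC21P, DGCR8, TOE1, POLR2J2, ANTKMT, TMEM74, FSTL1, POLR2G, SPG21, FAR1 and S100A16, and only WFDC21P was well above background on any array of the 4, on 1 siINSR array. Among those lower, NOP14, SRD5A3 and CDK12 were well above background on 1 siCont array, and CREB3L4, DYNC2I1, SLC25A14, ARSA, TEKT4P2 and SGMS1 on none with the probe tested. Another probe of CREB3L4 and of CDK12 was well above background on both siINSR arrays, and among measured genes their log2 changes were 0.07 and 0.04, not past the threshold. None of the 34 gene lists passed camera here; the smallest adjusted p was 0.106, for 3 lists, and with an estimated correlation 0.943. These were heat shock genes and histones upward and TGF-beta targets downward. At an unadjusted p under 0.05 there were 1232 genes, 403 higher and 829 lower. With the 75th percentile taken over all probes, the count was 77, 40 higher and 37 lower, and after quantile normalization 272, 143 higher and 129 lower. The direction turned with single arrays: 144 higher and 503 lower without 786-O_siCont replicate 1, 101 and 699 without 786-O_siCont replicate 2, but 277 and 122 without 786-O_siINSR replicate 1, and 314 and 145 without 786-O_siINSR replicate 2. The count was 3 among genes measured on these arrays. It was 0 without any 1 of the Caki-1 arrays, with normexp, with the replicate block, with only the arrays of the line and among probes above background on all arrays.

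Averaged over both lines, 6 genes passed limma's threshold. CCT8L2, WFDC21P and SELENOP were higher (limma adjusted p = 0.0299, 0.0369 and 0.0369), and CENPI, DYNC2I1 and CREB3L4 lower (limma adjusted p = 0.0317, 0.0399 and 0.0451). The average for CREB3L4 turned to 0.05 after quantile normalization, with another probe. In each direction the genes next in order did not pass: SNORA2B and POLR2G higher (limma adjusted p = 0.0516 for both), MGAM2 (limma adjusted p = 0.0516) and IGF2 (limma adjusted p = 0.0712) lower. No fold is given for these 10 genes, since the probe tested was at background in at least 1 group. CENPI alone of the 6 was measured in both lines. Camera called 5 lists: DNA replication (median log2 change 0.07, adjusted p = 0.00750), the interferon response (0.06, adjusted p = 0.00750), replication-dependent histones (0.02, adjusted p = 0.00750) and heat shock (0.05, adjusted p = 0.0104) upward, and ribosomal proteins (-0.07, adjusted p = 0.0104) downward. None passed with an estimated correlation, where the smallest adjusted p over the lists was 0.747. Many members were not measured on the arrays labelled 786-O: in both lines 9 of 30, 5 of 27, 9 of 14, 10 of 17 and 31 of 33 members were measured, in this order. On the arrays labelled 786-O alone, the DNA replication and interferon response medians were -0.12 and -0.14, against 0.20 and 0.18 in Caki-1. Their members measured on the arrays labelled 786-O had medians of 0.11 and 0.03, with 7 of 9 and 3 of 5 positive. The median of all genes on those arrays was -0.09 in this scaling, which the medians of the whole lists share in part. With so few members measured, a shift shared by both lines is not shown for these 2 lists. Among measured genes the heat shock (adjusted p = 0.207) and interferon response (adjusted p = 0.164) calls were lost. Over the settings tried, the calls were lost in 5 of 21 for DNA replication, 7 for the interferon response, 8 for histones, 11 for heat shock and 9 for ribosomal proteins. Single arrays moved the medians far. Without 786-O_siCont replicate 1 the histone median was 0.15 (adjusted p = 0.103), and without 786-O_siCont replicate 2 the DNA replication median 0.02 (adjusted p = 0.163), that of the interferon response 0.03 (adjusted p = 0.178) and that of heat shock 0.03 (adjusted p = 0.0788). Without Caki-1_siCont replicate 1 all 5 calls were lost, with the interferon response at 0.01 (adjusted p = 0.113). The ribosomal protein median was -0.01 after quantile normalization (adjusted p = 0.715). Adjusted over the list alone, 2 heat shock members and 1 histone gene passed: the chaperone genes HSPA1L and HSPB1, and the histone H3 gene H3C1, all higher. Only H3C1 was measured in both lines, and it was not well above background on the siCont arrays labelled 786-O. At an unadjusted p under 0.05 there were 1078 genes; the gene count was 18 with the percentile over all probes (12 higher, 6 lower) and 138 after quantile normalization (77 higher, 61 lower). It was 0 with normexp, with no filter on dim probes, among probes above background on all arrays and with the replicate block, and 2 among measured genes. Without siCont replicates 1 and 2 and siINSR replicates 1 and 2 in turn, it was 401, 520, 153 and 227 for the arrays labelled 786-O, and 28, 13, 4 and 28 for Caki-1. Most of these genes were lower without a siCont array and higher without a siINSR array. The number of lists called was 5, 1, 1 and 3 for 786-O, and 0, 7, 4 and 3 for Caki-1.

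Over 5415 genes measured in both, Pearson r was 0.072 and Spearman rho 0.093, across genes, which are not independent replicates. The value of r was -0.016 without 786-O_siCont replicate 1, 0.034 without 786-O_siCont replicate 2 and 0.025 without Caki-1_siINSR replicate 2. No gene was called the same way in both lines, but with 3 genes higher and 0 lower in Caki-1 the lists were too short for such a count to be informative. The difference between the 2 responses passed limma's threshold for 3 genes, all with a larger log2 change in Caki-1: CCT8L2 (limma adjusted p = 0.0285), CENPI (limma adjusted p = 0.0316) and CREB3L4 (limma adjusted p = 0.0410). Only CENPI was measured in both lines. No size is given, since each rests on a probe at background in at least 1 group, and the changes within a line have only the bounds above. The difference for CREB3L4 turned to -0.15 among measured genes and to -0.23 after quantile normalization, with another probe. DYNC2I1 and SRD5A3 followed (limma adjusted p = 0.0517 for both), and in the opposite direction WFDC21P (limma adjusted p = 0.0590), POLR2G (limma adjusted p = 0.0749), ANTKMT, NRN1 (limma adjusted p = 0.0911 for both) and FN3K (limma adjusted p = 0.128) did not pass. There were 1175 genes at an unadjusted p under 0.05. The count was 12 with the percentile over all probes (8 higher, 4 lower) and 131 after quantile normalization (60 higher, 71 lower). It was 0 with normexp, with no filter on dim probes, among probes above background on all arrays and with the replicate block. Without siCont replicates 1 and 2 and siINSR replicates 1 and 2 in turn, it was 391, 504, 122 and 234 for the arrays labelled 786-O, and 27, 12, 9 and 27 for Caki-1. Most of these differences were positive without a 786-O_siCont or Caki-1_siINSR array, and negative without one of the other 4.

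Beside control endothelial cells, the 2 lines differed at 13894 of 14838 genes, 10473 higher and 3421 lower in Caki-1 (limma). The split depended on the scaling: the median of all genes lay at 3.12 on the log2 scale in this fit, at -0.19 with the percentile over all probes (6445 higher and 7000 lower) and at 1.25 after quantile normalization (7373 higher and 5457 lower). Among the largest differences were genes without signal on the arrays labelled 786-O: the chemokine gene CXCL1 was at least 6949-fold higher in Caki-1, the HIF targets ANGPTL4 and NDRG1 at least 4637-fold and 4577-fold, the ribosomal protein gene RPS28 at least 4672-fold, the thymosin gene TMSB10 at least 3736-fold, TSR1 at least 3752-fold and the protein disulfide isomerase gene P4HB at least 3578-fold. In the other direction, AEBP1, LOXL1, COL1A2 and CDH11 were at least 6841-, 3624-, 1323- and 1099-fold lower in Caki-1, the platelet-derived growth factor receptor gene PDGFRA at least 1756-fold and the haptoglobin-related gene HPR at least 5493-fold. DLK1 had a mean of 15.23 ± 0.02 on the 2 siCont arrays labelled 786-O and 0.87 ± 0.08 (SD, n = 2) on those of Caki-1 with the probe tested. These are differences in probe signal, on arrays where probes of 1 gene often disagreed. The bounds hold for this scaling, and over the alternative settings the fitted log2 difference lay between 10.45 and 15.13 for CXCL1 and between -17.75 and -10.49 for AEBP1. Of 22 epithelial markers, 17 were well above background on all 4 Caki-1 arrays and 4 on all 4 arrays labelled 786-O; of 21 renal tubule lineage genes these numbers were 11 and 6. Of 16 mesangial, pericyte and fibroblast markers they were 7 and 8, with PDGFRA, THY1 and MYH11 above background on the arrays labelled 786-O and on no Caki-1 array, PDGFRB on Caki-1 arrays alone, and COL3A1, LUM and ITGA8 on no array of either line. These counts do not show levels. The markers above background on all arrays of both lines were brighter on the arrays labelled 786-O in this scaling. DCN lay at 16.44 (its brighter probe) against 5.95 in Caki-1, ACTA2 at 14.24 against 8.79 and COL1A1 at 13.27 against 4.25. DES lay at 8.97 against 7.53 and GATA3 at 6.84 against 5.54.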

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

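The results here come from tests of the difference between the 2 lines; the 3 list tests were added after the data were seen. For 3 genes the log2 change beside siINSR endothelial cells was larger in Caki-1 than on the arrays labelled 786-O: CCT8L2, CENPI and CREB3L4 (limma adjusted p = 0.0285, 0.0316 and 0.0410). The fitted differences, 2.97, 2.77 and 2.37, rest on probes at background and are not sizes of effect. CCT8L2 was well above background on the 2 Caki-1 siINSR arrays alone, where it was at least 1.84-fold higher than beside siCont. CENPI was near 5.02 in both Caki-1 groups, and on the arrays labelled 786-O it fell from 4.66 ± 0.21 (SD, n = 2) to background, at least 1.51-fold lower. For CREB3L4 the probe tested was not well above background on any array labelled 786-O. With another probe the difference turned, to -0.15 among genes measured in both lines and -0.23 after quantile normalization.

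Another 3 results, for gene lists, come from camera on the same difference, and with an estimated correlation none of them passed (adjusted p = 0.996). The DNA replication list had a median difference of 0.30 (adjusted p = 0.0319), with medians of 0.20 in Caki-1 and -0.12 on the arrays labelled 786-O. For the TGF-beta targets the median difference was 0.19 (adjusted p = 0.0184), with medians of 0.06 and -0.15, and for the ribosomal proteins -0.086 (adjusted p = 0.00402, and 0.996 for each of the 3 lists with an estimated correlation), with medians of -0.14 and -0.03. The call for the TGF-beta targets was lost after quantile normalization (0.09, adjusted p = 0.148) and without 786-O_siCont replicate 1 (0.13, adjusted p = 0.0533), 786-O_siCont replicate 2 (0.31, adjusted p = 0.117) or 786-O_siINSR replicate 1 (0.20, adjusted p = 0.125), and with normexp it held with a median of -0.02. The call for the ribosomal proteins turned after quantile normalization (0.0079, adjusted p = 0.910). It was lost with normexp (adjusted p = 0.769), above background on all arrays (adjusted p = 0.0784), among measured genes (adjusted p = 0.0860) and without 786-O_siINSR replicate 1 (adjusted p = 0.125) or Caki-1_siINSR replicate 2 (-0.05, adjusted p = 0.110). The call for DNA replication was lost after quantile normalization (0.23, adjusted p = 0.148), above background on all arrays (0.09, adjusted p = 0.590), with array weights (adjusted p = 0.0572) and among measured genes (0.10, adjusted p = 0.268). It was also lost without 786-O_siCont replicate 1 (0.17), 786-O_siINSR replicate 2 (0.31), Caki-1_siCont replicate 1 (0.16) or Caki-1_siINSR replicate 2 (0.22), with adjusted p from 0.239 to 0.442.

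In this scaling the median of all genes was 0.08 for the difference and -0.09 on the arrays labelled 786-O, against 0.01 and -0.03 with the percentile over all probes. On the arrays labelled 786-O only 9 of 30 DNA replication genes and 9 of 22 TGF-beta targets were measured, and the 9 DNA replication genes had a median of 0.11 there, opposite in sign to the whole list, so this difference rests largely on probes at background.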

How the results depend on the processing

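The main scaling, by the percentile over probes well above background on all arrays, was chosen after seeing the data. So were normexp on median signal, both fits restricted to genes measured in the comparison, and the set test on the difference between lines. The percentile over all probes was the planned scaling and is given here as an alternative. Normexp on mean signal was not run, since the files hold no such column, nor was a slide or scan block, since there was 1 slide and 1 scan. Each fit that leaves out an array keeps 1 array in a group, which is assumed to vary like the others. Unless the setting tests fewer genes or arrays, the cause was not tested.

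Gene counts were unstable. For the arrays labelled 786-O (51 genes in limma) the count was 77 with the percentile over all probes, 0 with normexp on median signal, 272 after quantile normalization, 28 with no filter, 0 among probes above background on all arrays, 0 with only the arrays of the line, 15 with array weights, 0 with the replicate block, 3 among genes measured in the comparison and 12 among these with eBayes trend and robust; leaving out 1 array gave 0 to 800. For Caki-1 (3 genes) these were 1 with all probes, 0 after quantile normalization, 1 with no filter, 0 above background on all arrays, 8 with probes tested separately, 0 with only the arrays of the line, 14 with array weights, 0 with the replicate block and 1 in both measured fits; leaving out 1 array gave 0 to 41. For the average (6 genes) they were 18, 0 with normexp, 138 after quantile normalization, 0 with no filter, 0 above background on all arrays, 3 with probes tested separately, 0 with the replicate block, 18 from the authors' table and 2 in both measured fits; leaving out 1 array gave 4 to 520. For the difference between responses (3 genes) they were 12, 0 with normexp, 131 after quantile normalization, 0 with no filter, 0 above background on all arrays, 1 with the mean of probes, 7 with probes tested separately, 5 with eBayes trend and robust, 7 with array weights, 0 with the replicate block, 9 from the authors' table and 6 among measured genes with trend and robust; leaving out 1 array gave 9 to 504. The replicate numbers did not pair the arrays, with correlations of their deviations of -0.046 and -0.025 in 786-O and Caki-1. Between lines, 4718 genes differed among those above background on all arrays, where fewer were tested, and 24233 probes when tested separately, where more were.

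Lists called on the arrays labelled 786-O (0) were 3 with normexp, 3 above background on all arrays and 3 in both measured fits. In Caki-1 (7) they were 0 with an estimated correlation and 3 after quantile normalization, and leaving out 1 array gave 3 to 7. For the average (5) they were 0 with an estimated correlation, 3 after quantile normalization, 2 above background on all arrays and 3 in both measured fits, and leaving out 1 array gave 0 to 7. For the difference (3) they were 0 with an estimated correlation, 5 with normexp, 0 after quantile normalization, 5 with no filter and 1 above background on all arrays, and leaving out 1 array gave 1 to 8. Over all settings, list calls were kept in 227 of 321 runs, lost in 93 and turned in 1, the ribosomal proteins in the difference (0.0079 after quantile normalization). In Caki-1 the DNA replication and interferon response calls were lost with the estimated correlation alone. The correlation of fold changes (0.072) was 0.14 with normexp, 0.030 with no filter, 0.0027 with the mean of probes and 0.10 with probes tested separately, and leaving out 1 array gave -0.016 to 0.089. INSR passed under no setting; in Caki-1 it ranged from -0.49 to 0.01 when 1 array was left out.

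Of 661 runs of called genes, 365 kept direction and call, 279 kept direction alone and 17 reversed, where another probe of CREB3L4 or CDK12 was chosen. CREB3L4 in 786-O was then 0.16 after quantile normalization, 0.070 in both measured fits and 0.072 without any 1 Caki-1 array (leaving out 1 array gave -2.36 to 0.072); its average was 0.046 after quantile normalization and 0.072 without Caki-1_siINSR replicate 2 (-1.10 to 0.072); its difference was -0.23 after quantile normalization, -0.15 in both measured fits and -0.32 to -0.14 without 3 of the 4 Caki-1 arrays in turn (-0.32 to 2.51 over all 8 arrays). CDK12 in 786-O was 0.039 in both measured fits. Signal over background limits the arrays labelled 786-O most: 5986 of 14838 genes were measured there, against 14267 in Caki-1.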

Other observations

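The tests of the arrays labelled 786-O, the endothelial test and the trend test on 2 lists were chosen after the result was seen. Of the lists that did not pass camera in Caki-1, the angiogenic factors had a median log2 change of -0.14 with 12 of 20 measured members lower, the ATF4 targets, genes of the amino acid stress response, -0.07 with 17 of 24 lower, and the NF-kB inflammatory genes -0.08 with 18 of 30 lower (adjusted p = 0.140, 0.275 and 0.292). Glycolysis genes (-0.04), cholesterol synthesis genes (-0.00) and oxidative phosphorylation genes (0.02) lay near 0, with adjusted p of 0.877, 0.908 and 0.877.

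On the arrays labelled 786-O many probes that were bright in Caki-1 were at background. Misread spot positions are argued against by the spike-in controls, whose lowest R squared on the 4 arrays was 0.986. Weaker labelling alone is argued against because 35.8% of the 1000 brightest Caki-1 probes were below background on all 4 arrays. Loss of 5' ends as the whole cause is argued against by the short ribosomal protein transcripts, of which 27.3% of 161 probes were lost as well. Over all probes 13803 of 23427 were lost, a larger share, so a part played by such loss stays open. A different human cell type as the whole cause is argued against by ribosomal proteins, which every human cell type makes. Of their 123 probes among the 1000 brightest in Caki-1, 20.3% (Wilson 95% interval 14.2% to 28.3%) were below background on all 4 arrays. This share is below the 35.8% of all 1000, and the interval treats probes of 1 gene as independent. Of 33 ribosomal protein genes in the fixed list, 31 were measured on the arrays labelled 786-O. Signal was thus missing for probes rather than for most of these genes. The split of probes within genes does not decide about the cell type, since the gap between directions (40.3% against 2.02%) follows from how many probes were lost each way. A candidate explanation, as a hypothesis, is RNA whose sequence differs from the human probes, such as that of another species; it stays open, since non-coding probes, expected to lose signal more often, lost it less often than coding probes of like Caki-1 brightness (a difference of -7.94 percentage points), and the probe sequences were not used here.

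Of the list shifts in Caki-1, when a trend of the fold change with signal was taken out, 4 of the 7 lists kept their call and direction, and the ribosomal proteins (median from -0.14 to -0.02, adjusted p = 0.906), HIF targets (from -0.14 to -0.11, adjusted p = 0.116) and unfolded protein response (from -0.07 to -0.03, adjusted p = 0.184) lost it. Such a trend may account for the ribosomal proteins, whose median moved close to 0. It stays open for the unfolded protein response, which lost most of its shift, and for the HIF targets, which kept most of theirs. DNA replication and the interferon response, picked after they had kept their call, moved little, from medians of 0.20 and 0.18 to 0.19 and 0.16. Their larger adjusted p was then 0.000428 (camera, preset correlation). This argues against the trend as the whole cause of these 2 shifts. It does not bear on the estimated correlation, where neither list passed. Single arrays mattered: 3 of the 7 lists, DNA replication, the interferon response and the ribosomal proteins, kept their call whichever of the 4 Caki-1 arrays was left out. Some medians moved far: without Caki-1_siCont replicate 1 cell division fell from 0.13 to 0.06, metallothioneins from -0.22 to -0.13 and HIF targets from -0.14 to -0.09, and without Caki-1_siINSR replicate 1 HIF targets fell to -0.07 and the unfolded protein response from -0.07 to -0.04. Others moved little as the call was lost: metallothioneins were at -0.20 without Caki-1_siINSR replicate 1, cell division at 0.10 without Caki-1_siINSR replicate 2, and the unfolded protein response between -0.07 and -0.06 in its other 3 fits. Endothelial RNA in the Caki-1 wells stays open. Of 25 endothelial markers with a named probe, 8 were well above background on all 4 Caki-1 arrays. The 8 did not include PECAM1, CDH5 or KDR. The brightest of them, EGFL7, NOS3 and SOX17, had means of 9.22, 8.59 and 8.55 beside siCont cells. Whether this signal came from Caki-1 or from endothelial cells was not tested, so the marker changes need not report carry-over. The 8 measured markers had a median log2 change of 0.085, with 5 higher and 3 lower. Among them S1PR1 was at 0.38, against VWF at -0.27 and ROBO4 at -0.31, with siCont means of 3.71, 3.80 and 4.01. These 3 lay near the lowest signal of probes well above background on the Caki-1 arrays, between 2.70 and 3.13. The brighter markers were SOX17 at 0.25, ENG at 0.11, NOS3 at 0.09, EHD3 at 0.08 and EGFL7 at -0.03. A response of Caki-1 cells to the endothelial knockdown was not separable from position on the slide.

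For the average over both lines, other splits of the 8 arrays decided nothing: in a model with the line the real split called 0 genes and the highest of the other splits 1, and against a count of 0 all 34 splits that could be fitted count as being as large by construction.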
